A study of Mus musculus with 8 samples.

How the data were processed

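RNA was measured in LSK cells of 8 libraries, 4 WT and 4 KO, grouped by the genotype and title in the labels. Per the labels' protocols, 100 ng of total RNA was enriched for poly(A) RNA, fragmented with RNase III, ligated to adaptors and reverse transcribed. The protocols name a paired-end flow cell and, in the series design, a single-read flow cell with 50 bp reads, so the read layout is not settled here. Per the submitters' processing notes, TopHat, edgeR and the mouse build mm9 were used, with no version or role given; the counting tool, annotation and filters are not given in the sources used here.

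The deposited values are RPKM as made by the authors, with 1 value per Entrez gene and library. The unit is inferred from the values, since neither the labels nor the tables state it: values times transcript length sum to between 1.02 and 1.04 M in each library (M, mega), and low values come in steps that go with 1 over length. Of 24112 gene IDs, 24029 (99.7%) were matched to a symbol in a GRCm38 gene table, which was used for names only; no coordinates are given because the build differs. The 83 others were kept by ID. Of all genes, 8722 were at 0 in every library.

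Because the RPKM are not counts, depth had to be estimated. Low values, up to 0.2 RPKM, of 6522 genes with a lone protein-coding transcript were compared with the value of 1 read, which gave 19.3 to 30.7 M reads in genes per library. Between 42.0% and 64.7% of the 75 to 193 values compared in a library were whole numbers of reads within 0.03 reads. The depth is therefore approximate, whole reads could not be recovered, and no count test was run. The number of genes listed above 0 did not follow this depth, and no interval for counting error is given.

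Groups, tests, gene lists and the rule for naming genes were fixed before the data were examined, with a test for counts and a test for RPKM foreseen; the latter applied. Values were tested as log2(RPKM + 1) in genes with at least 1 RPKM in at least 4 libraries (11276 genes), with limma 3.58.1 in R 4.3.3 (linear model of genotype on all 8 libraries, eBayes with trend and robust variance) and Benjamini-Hochberg adjusted p under 0.05. Log2 differences are KO minus WT on that scale, ± SE, and levels are mean RPKM ± SD with n = 4 per group. 2-sided exact permutation tests used all 70 assignments of the libraries.

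Of 27 gene lists fixed from background knowledge, 26 with at least 5 tested members were tested with limma's camera (preset correlation 0.01, adjusted over the 26 lists), with camera's estimated correlation and with fry; sex-linked genes served as a check of samples. The lists covered NF-κB targets, TRAF6 signalling, stem and progenitor classes, mature blood, stromal and endothelial cells, cell cycle, kinase inhibitors, p53, interferon, MHC class II, immediate-early genes, the unfolded protein and heat shock responses, oxidative phosphorylation, glycolysis, ribosomal proteins, TGF-β and apoptosis. The exact permutation of list levels was added after the data were seen.

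Genes were named by a rule: Traf6; up to 12 rises and 12 falls past the threshold without overlap between groups or, where fewer passed, up to 5 that missed it with the smallest p; up to 4 members per list past the threshold or the 2 of highest expression; and all cyclin-dependent kinase inhibitors tested. Genes called with library weights, members of smallest p in the called lists, members past the threshold adjusted over a list alone, and the NF-κB and sorting marker genes were added after their values were seen. Some of the genes chosen in these ways are not reported here; all remained in the fits and lists.

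Alternatives fixed in advance were the filter on low values, the pseudocount (0.1), lane as a covariate, lane 4 alone, the replicate number as a block, leaving out ribosomal protein, haemoglobin and mitochondrial genes, an adjusted p under 0.1, a fold minimum and leaving out each library. Library weights (limma's arrayWeights), quantile normalization, centring on highly expressed genes, the number of genes listed as a covariate, genes above 20 RPKM on average, and leaving out WT2, KO3 and KO4 were added after the data were seen. No 2 libraries of a group held identical values: at most 6.86% of tested genes shared a value, in KO3 and KO4, which list many genes at 0.

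The tests were checked on simulated data of 11276 genes with known changes in some of them. Changed genes were drawn only from those with a mean log2(RPKM + 1) above 2, so recovery of lower genes was not checked. With no change, limma called 0 genes in each of 20 draws and the weighted fit called at most 1. With log2 changes of 1, 2 and 4, the weighted fit recovered 46.0%, 84.3% and 98.5% of changed genes with 4.33% false calls, on noise drawn with those same weights, against 0.577% false calls without weights. Camera called the shifted list in 20 of 20 draws and 0 of 500 unshifted lists. The noise was drawn independently for each gene, so this check could not show false calls from genes that vary together. In the real data the estimated correlation within the 8 called lists was 0.071 to 0.437. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.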

Results

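TRAF6 is a ubiquitin ligase and adaptor that passes signals from Toll-like and interleukin-1 receptors to the transcription factor NF-κB. The study asked whether TRAF6 sustains a basal level of NF-κB activity that blood stem cells need for their maintenance. Lineage-negative Sca1+ Kit+ (LSK) cells, the bone marrow fraction enriched for hematopoietic stem and early progenitor cells, were sorted from C57BL/6 mice after transplantation. The donor marrow carried the Cre recombinase driven by the Vav promoter, which acts in blood cells, either alone (wild type, WT, 4 libraries) or together with loss of Traf6 (KO, 4 libraries). Poly(A) RNA was sequenced, and each library is a list of 24112 genes with values in RPKM (reads per kilobase of gene, scaled to the reads of the library). Nothing in the labels states that the 4 libraries of a group came from separate mice, so p-values measure the spread between these libraries, which may be technical.

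Depth was read from the steps between low values and is an estimate. The WT libraries held about 20.5, 19.3, 20.3 and 24.9 megareads (M reads) in genes, and the KO libraries about 30.7, 30.1, 22.6 and 25.3 M reads. The number of genes listed above 0 was 12754, 11169, 12861 and 12970 in WT and 13571, 13689, 9055 and 10674 in KO. The means were 12438.5 ± 850.9 and 11747.25 ± 2272.8 (SD, n = 4), which did not differ in a 2-sided exact permutation test (p = 0.686). KO3 and KO4 listed the fewest genes, although their estimated depth exceeded that of WT1 to WT3. Of 3943 genes with a mean above 20 RPKM, KO3 listed 175 at 0 (4.44%), KO4 listed 61, WT2 listed 47, and the other 5 libraries listed 6 to 20. A value of 0 is therefore written below as listed at 0, and it does not show that a transcript was absent. KO3 and KO4 were sequenced in lane 5 and the other 6 libraries in lane 4, so lane and genotype overlap in part. The first 3 principal components held 44.5%, 19.4% and 16.8% of the variance, and each set a single library apart: KO3, KO4 and WT2, respectively.

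Traf6 (Entrez 22034) was low in every KO library. Its values were 14.9, 3.52, 9.40 and 7.10 RPKM in WT1 to WT4, against 0.613, 0.818, 0 (listed at 0) and 0.00721 RPKM in KO1 to KO4. All 4 KO values lay below all 4 WT values (2-sided exact permutation p = 0.0286, the smallest that 70 assignments of 4 and 4 libraries can give). On the log2(RPKM + 1) scale, which understates the change of low genes, the difference was -2.75 ± 0.53 (SE, n = 4 per group). Its limma adjusted p over all 11276 genes tested was 0.341, past no threshold, and with a pseudocount of 0.1 the difference was -4.75. A value for the whole gene also counts exons that a conditional deletion can leave in place.

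**Figure D1:**
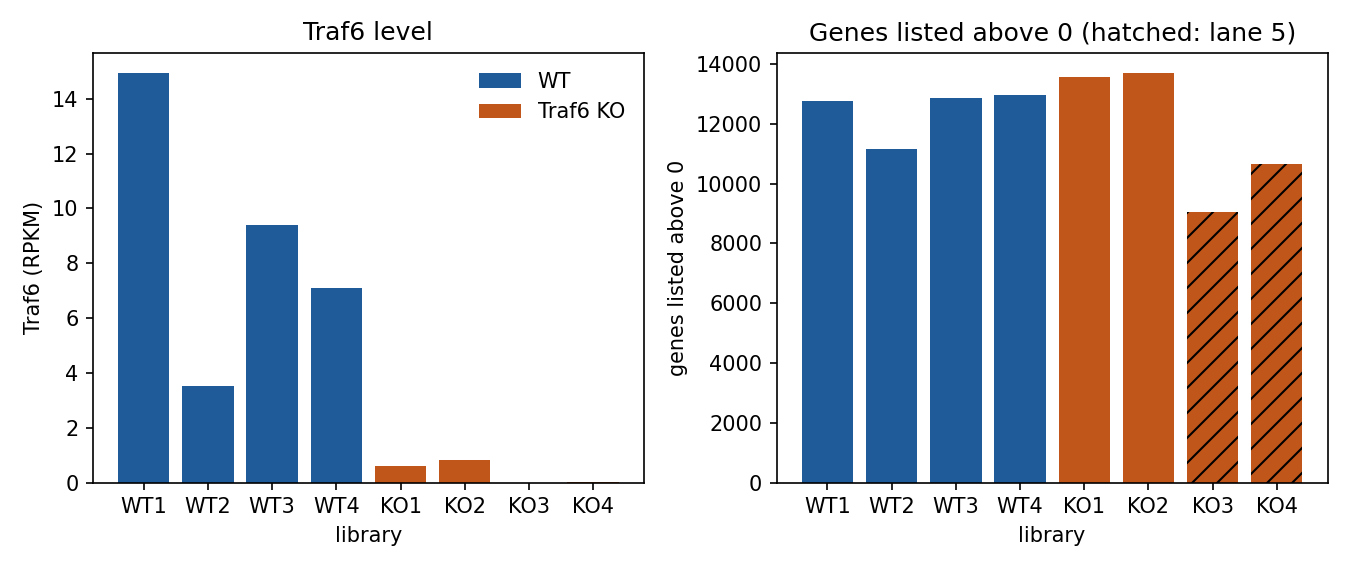
Traf6 in RPKM (left) and the number of genes listed above 0 (right) in each of the 4 WT and 4 KO libraries, 1 bar per library, with the lane 5 libraries hatched. Traf6 lay between 3.52 and 14.9 RPKM in WT and at or below 0.818 RPKM in KO, and KO3 and KO4 listed 9055 and 10674 genes.

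None of the genes of smallest p passed the threshold once adjusted over all genes. Among the falls of smallest p were Gimap6 (231931), a GTPase of the immunity-associated family, at 88.4 ± 14.1 RPKM in WT and 18.9 ± 8.11 in KO (log2 difference -2.25 ± 0.30, adjusted p = 0.238). Jchain (16069), the joining chain of polymeric antibodies, was at 31.2, 24.4, 26 and 18.4 RPKM in WT and at 1.88, 1.40, 0 and 5.73 in KO. Gbp2b (14468), an interferon-induced GTPase, was at 6.39 to 16.3 RPKM in WT, at 0.859 in KO2 and listed at 0 in the other 3 KO libraries. Ifi44l (15061) was at 3.19 to 8.06 RPKM in WT and listed at 0 in all 4 KO libraries. Erdr1 (170942) was at 177 ± 31.4 RPKM in WT and 57.2 ± 22.5 in KO (-1.68 ± 0.29). Among the rises was Ifitm3 (66141), a membrane protein that restricts viral entry, at 147 ± 19.2 and 281 ± 33.8 RPKM (0.93 ± 0.16, adjusted p = 0.298). Bace1 (23821), Ubash3a (328795) and the small nucleolar ribonucleoprotein gene Nhp2 (52530) had log2 differences of 1.46 ± 0.30, 1.77 ± 0.39 and 0.78 ± 0.17. The adjusted p of these 9 genes lay between 0.238 and 0.441 in limma. In each of them all 4 KO values lay on one side of all 4 WT values, because the naming rule admitted only such genes. They are thus the genes of smallest p among those without overlap, and the separation adds no evidence. Gimap and Gbp genes have near-identical relatives, so their reads may be split among copies.

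Across the 11276 genes tested with limma, 0 passed an adjusted p of 0.05, 0 were higher and 0 were lower. At an unadjusted p under 0.05 there were 847 genes, 312 higher and 535 lower in KO, where 563.8 would be reached by chance; without WT1 there were 553. The 2 groups did not overlap in 668 genes (5.92%), against 2.86% by chance. The median log2 difference of all genes was -0.14 and moved to 0.00 with quantile normalization, so groups of genes are given below relative to all genes tested. Counts of members with negative or positive log2 differences are not set relative to all genes. Since the median lay below 0, most genes tested were negative, so a majority of negative members is not by itself a fall. In simulated data of the same spread, this test recovered 11.8% of genes changed by 1 on the log2 scale, 54.5% of those changed by 2 and 89.2% of those changed by 4. The changed genes all had a mean log2(RPKM + 1) above 2, so these shares do not cover lower genes. Without KO3, Gem and Gimap6 passed the threshold as lower, and in the lane 4 libraries alone Gem and Jchain did. Gem, a small GTPase, was at 55.6, 28.7, 25 and 20.2 RPKM in WT and at 0.578, 1.10, 11.7 and 0 in KO.

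A fit that gave each library a weight by how closely it followed its group was added after the values had been seen. It gave KO3 and KO4 weights of 0.137 and 0.351 and KO2 a weight of 6.50, so the KO side rested largely on KO2. With these weights limma called 164 genes, 67 higher and 97 lower. Traf6 was among them (-2.52, adjusted p = 0.00785), with falls of Jchain (-3.30), Gem (-3.89), Emp1 (-2.77), Gimap7 (-2.41) and Rrad (-2.27), and rises of Csf1r (2.26), Ctsg (2.06), Itgam (1.64) and Rrp9 (1.34). The count was 0 without KO1, 1 without KO2, 8 without WT3, 34 without WT2, 58 without WT1, 60 without KO4 and 248 without KO3. It was 49 in the lane 4 libraries alone, 59 with lane as a covariate and 6 without WT2, KO3 and KO4.

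Of 26 gene lists tested with camera, 4 rose and 4 fell in KO at an adjusted p under 0.05 with its preset correlation between genes. Granulocyte-monocyte progenitor genes, chaperones of the unfolded protein and heat shock responses, glycolysis genes and oxidative phosphorylation genes rose relative to all genes tested. Immediate-early and AP-1 genes, long-term stem cell genes, MHC class II genes and NF-κB target genes fell. None of the 8 calls held when the correlation was estimated from these libraries (0 of 26, smallest adjusted p = 0.327) or with fry (0 of 26, smallest adjusted p = 0.0757). An exact permutation of list levels passed 0 of 26 (smallest adjusted p = 0.106), but 8 libraries cannot give it an unadjusted p under 0.0286, so it could hardly pass any list once adjusted, and it decides nothing about the calls; 7 lists lay at that minimum. No list had a member past the threshold over all genes, and 10 of 26 had at least 1 when adjusted over the list alone. The level of a list in a library is the mean log2(RPKM + 1) of its tested members minus that of all genes tested.

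**Figure D2:**
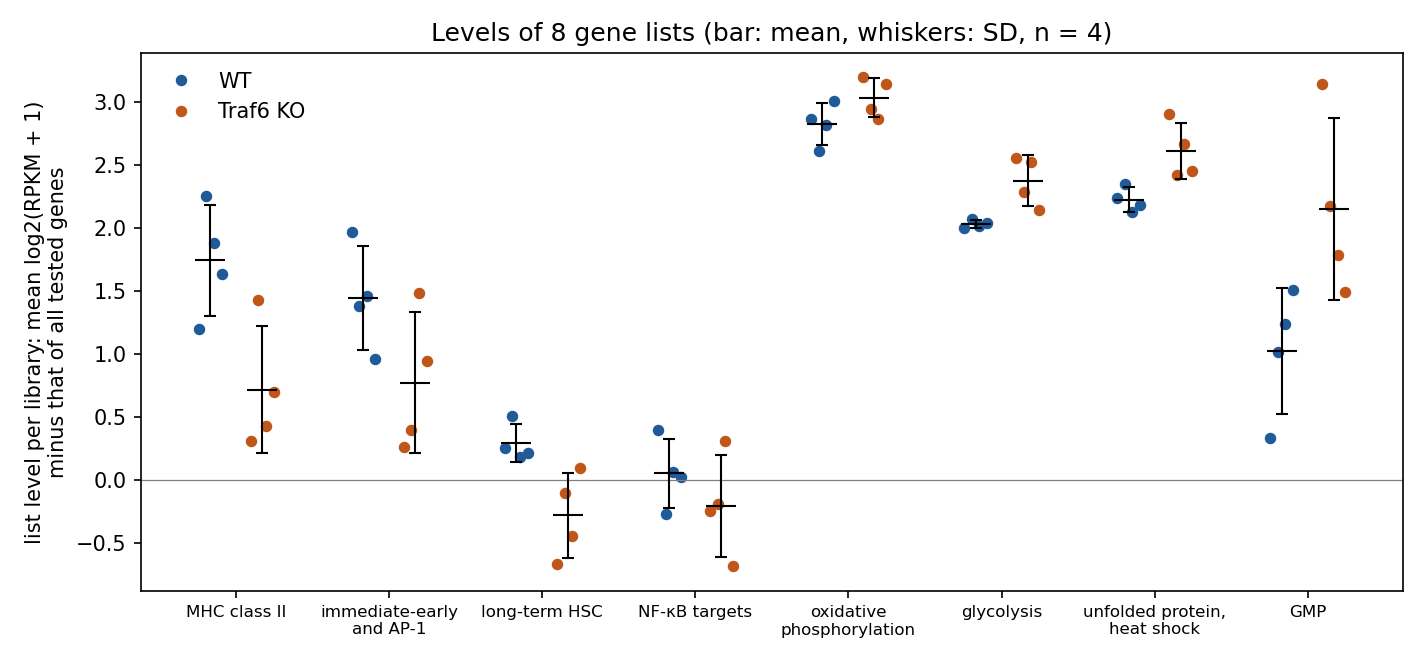
Level of the 8 lists called with camera, as mean log2(RPKM + 1) of the tested members minus that of all genes tested, with 1 point per library and the mean ± SD of the 4 WT and 4 KO libraries. Granulocyte-monocyte progenitor genes lay at 1.03 ± 0.50 in WT and 2.15 ± 0.72 in KO, and immediate-early and AP-1 genes at 1.45 ± 0.41 and 0.77 ± 0.56.

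Immediate-early genes are induced within minutes of a stimulus and include the FOS and JUN subunits of AP-1. They fell as a group in KO: 30 of 33 tested members had negative log2 differences, and the list level was 1.45 ± 0.41 in WT and 0.77 ± 0.56 in KO (difference -0.67, camera adjusted p = 3.0e-10). With an estimated correlation the adjusted p = 0.327, and the exact permutation p of the level was 0.171. Adjusted over the list alone, 9 members fell (0 over all genes). They were the AP-1 genes Fosb, Junb and Jund, the stress-induced factor Atf3, the MAP kinase phosphatases Dusp6 and Dusp2, Ier5, and the Krüppel-like factors Klf6 and Klf2. Fosb went from 137 ± 36.0 to 49.7 ± 13.2 RPKM (-1.44 ± 0.27, SE), Dusp6 from 34.5 ± 8.22 to 13.2 ± 5.21 (-1.37 ± 0.32) and Junb from 245 ± 82.5 to 138 ± 14.7 (-0.78 ± 0.22). The 2 members of highest expression missed the threshold: Fos was at 429 ± 26 and 296 ± 147 RPKM (-0.66 ± 0.30), and Ier2 at 421 ± 56.1 and 321 ± 85.8 (-0.42 ± 0.21). The lane 5 libraries KO3 and KO4, at list levels of 1.49 and 0.95, overlapped WT, and KO1 and KO2 lay at 0.27 and 0.40. In lane 4 alone the difference was -1.11, and without WT2, KO3 and KO4 it was -1.13. Here and below, both settings take the KO side from KO1 and KO2 only, as does lane as a covariate, so they are not separate checks. The count of 9 became 2 without WT3, 3 without KO1, 4 without WT1, WT2 or KO2, and 16 without KO3.

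NF-κB target genes, the pathway named by the study's question, were lower by a smaller margin. Of 44 tested members 35 had negative log2 differences, the list level was 0.05 ± 0.27 in WT and -0.20 ± 0.41 in KO, and the difference was -0.26 (camera adjusted p = 0.0450). Relative to all genes, the median member lay at -0.12. With an estimated correlation the adjusted p = 0.359, and the exact permutation p was 0.343. No member passed the threshold over all genes or adjusted over the list alone. The members of smallest p, chosen after their values were seen, were Tnfaip3, which encodes the NF-κB inhibitor A20, at 21.9 ± 12.7 RPKM in WT and 5.15 ± 2.62 in KO (-1.83 ± 0.45), Sdc4, at 1.16 to 2.45 RPKM in WT and listed at 0 in all KO libraries, and the kinase gene Map3k8, at 1.60 to 4.78 RPKM in WT and 0.403, 1.11, 0 and 0 in KO. Nfkb1 and Nfkb2, which encode NF-κB subunits, had log2 differences of -0.05 ± 0.25 and -0.09 ± 0.54, and Nfkbia, which encodes IκBα, had -0.66 ± 0.37. These 3 genes were also chosen after their values were seen; the differences of Nfkb1 and Nfkb2 lay within their SE of 0 and changed sign with the libraries used. Of the tested members Junb, Zfp36, Ier3 and Gadd45b belong to this list and to the immediate-early list, so the falls of the lists are not independent. Zfp36 was at 397 ± 112 and 271 ± 104 RPKM (-0.58 ± 0.30). The call was lost without WT1 (difference -0.14, adjusted p = 0.172), KO1 (-0.24, 0.0886), KO2 (-0.26, 0.0865) or KO4 (-0.10, 0.307) and in lane 4 alone (-0.27, 0.0855), and the difference was -0.43 without KO3 and -0.38 without WT2, KO3 and KO4.

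The genes of the pathway around TRAF6 itself, from receptors to kinases, gave a list level of -0.37 ± 0.10 in WT and -0.60 ± 0.19 in KO, with 38 of 48 members negative (difference -0.23, camera adjusted p = 0.0525). No member passed the threshold, over all genes or adjusted over the list alone. Its members of highest expression were the ubiquitin-conjugating variant Ube2v1, at 95.1 ± 13.7 and 101 ± 4.12 RPKM, and the p38 kinase gene Mapk14, at 93.7 ± 9.01 and 85.1 ± 21.0. The list passed in 6 of 22 settings, among them without WT3 (adjusted p = 0.0493), WT4 (0.0343), KO1 (0.0459) or KO2 (0.0435).

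Genes typical of long-term stem cells fell as a group. Of 43 tested members 39 had negative log2 differences, and the list level was 0.29 ± 0.15 in WT and -0.28 ± 0.34 in KO (difference -0.57, camera adjusted p = 1.1e-05). With an estimated correlation the adjusted p = 0.327, and the exact permutation p was 0.0286, with all KO levels below all WT levels. Adjusted over the list alone, Gimap6 and the cyclin-dependent kinase inhibitor Cdkn1c fell and Ifitm3 rose; the other 40 members did not pass. Cdkn1c, which encodes p57 and restrains stem cell division, was at 3.98, 5.33, 3.86 and 4.43 RPKM in WT and at 1.30, 1.28, 0 and 0 in KO. It passed in none of the 8 fits that left out a library, whereas Gimap6 and Ifitm3 passed in all 8. Procr, the endothelial protein C receptor used to sort stem cells, was at 19.6 ± 6.40 and 7.92 ± 4.45 RPKM (-1.27 ± 0.38) and missed the threshold. Adjusted over the list alone, Procr, Hlf and Socs2 passed without KO4 and in lane 4 alone, but in no other fit that left out a library. The 2 members of highest expression were Zfp36l2, at 818 ± 159 and 622 ± 176 RPKM (-0.42 ± 0.23), and Adgrg1, at 324 ± 36.6 and 292 ± 106 (-0.23 ± 0.26). In lane 4 alone the list difference was -0.68, and without WT2, KO3 and KO4 it was -0.60.

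Genes of granulocyte-monocyte progenitors, the myeloid-committed cells downstream of the LSK fraction, rose in KO. Of 25 tested members 23 had positive log2 differences, and the list level was 1.03 ± 0.50 in WT and 2.15 ± 0.72 in KO (difference 1.13, camera adjusted p = 2.2e-11). The adjusted p with an estimated correlation was 0.327, and the exact permutation p was 0.0571. In limma adjusted over the list alone, 4 members rose (0 over all genes): the granule protein genes Mpo and Ctsg and the myeloid transcription factor genes Cebpa and Irf8. Mpo, myeloperoxidase, was at 757 ± 292 RPKM in WT and 2180 ± 1063 in KO (1.52 ± 0.40), and Ctsg, cathepsin G, at 46.2 ± 12 and 190 ± 157 (1.70 ± 0.50). Cebpa was at 8.57 ± 3.74 and 20.6 ± 6.30 RPKM (1.22 ± 0.36), and Irf8 at 17.9 ± 9.18 and 37.1 ± 4.51 (1.14 ± 0.34). The most abundant member, the endoplasmic reticulum chaperone gene Calr, was at 1215 ± 128 and 1945 ± 827 RPKM (0.60 ± 0.25) and missed the threshold. KO1 carried the highest level (3.15, with Mpo at 3687 RPKM), and KO4, at 1.49, lay just below WT4 at 1.51. The count of 4 became 0 without WT1, WT2, WT4, KO1 or KO2, 1 without WT3, and 7 without KO3 or KO4. In lane 4 alone the list difference was 1.64, and without WT2, KO3 and KO4 it was 1.63.

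Multipotent and lymphoid-primed progenitor genes went both ways and did not pass as a group (level 1.29 ± 0.04 in WT and 1.02 ± 0.15 in KO, difference -0.27, camera adjusted p = 0.117). Adjusted over the list alone, members that fell were the cytokine receptor gene Flt3, Gpr171 and Jchain, and those that rose included Plac8. Flt3 was at 78.1 ± 13.3 RPKM in WT and 45.0 ± 10.4 in KO (-0.80 ± 0.23), Gpr171 at 18.6 ± 7.44 and 6.37 ± 2.41 (-1.39 ± 0.40) and Plac8 at 1899 ± 552 and 3039 ± 262 (0.71 ± 0.18). Jchain alone passed without WT1, WT2, WT3 or KO1, and 8 members passed without KO4. Cd34 was at 259 ± 26.1 and 232 ± 44.4 RPKM. The list passed in 6 of 22 settings, among them without KO3 (-0.29, adjusted p = 0.0394) and in lane 4 alone (-0.37, 0.0123).

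MHC class II genes, which encode the molecules that present peptides to helper T cells, were lower in KO. Of 9 tested members 8 had negative log2 differences, and the list level was 1.75 ± 0.44 in WT and 0.72 ± 0.50 in KO (difference -1.03, camera adjusted p = 4.5e-04). The adjusted p with an estimated correlation was 0.327, and the exact permutation p was 0.0571. In limma adjusted over the list alone, 5 members fell (0 over all genes): H2-Aa, H2-Ab1, H2-Eb1, H2-Ob and the invariant chain gene Cd74. H2-Aa went from 262 ± 101 to 53.6 ± 43.1 RPKM (-2.61 ± 0.59), H2-Ab1 from 239 ± 66.5 to 107 ± 34.5 (-1.18 ± 0.30) and Cd74 from 174 ± 72.7 to 55.8 ± 29.0 (-1.74 ± 0.45). H2-Eb1 was at 50.5 to 107 RPKM in WT and at 4.32, 20.9, 0 and 31.6 in KO. Dendritic cell genes lay lower alongside, by -0.86 ± 0.35 on the log2 scale over 4 genes above 0 in any library, at no more than 4.67 RPKM on average. In lane 4 alone the list difference was -0.88 (adjusted p = 0.0113). Without WT2, KO3 and KO4 it was -0.70 and did not pass (adjusted p = 0.0940), nor did it pass with library weights (-0.49, 0.111).

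**Figure D3:**
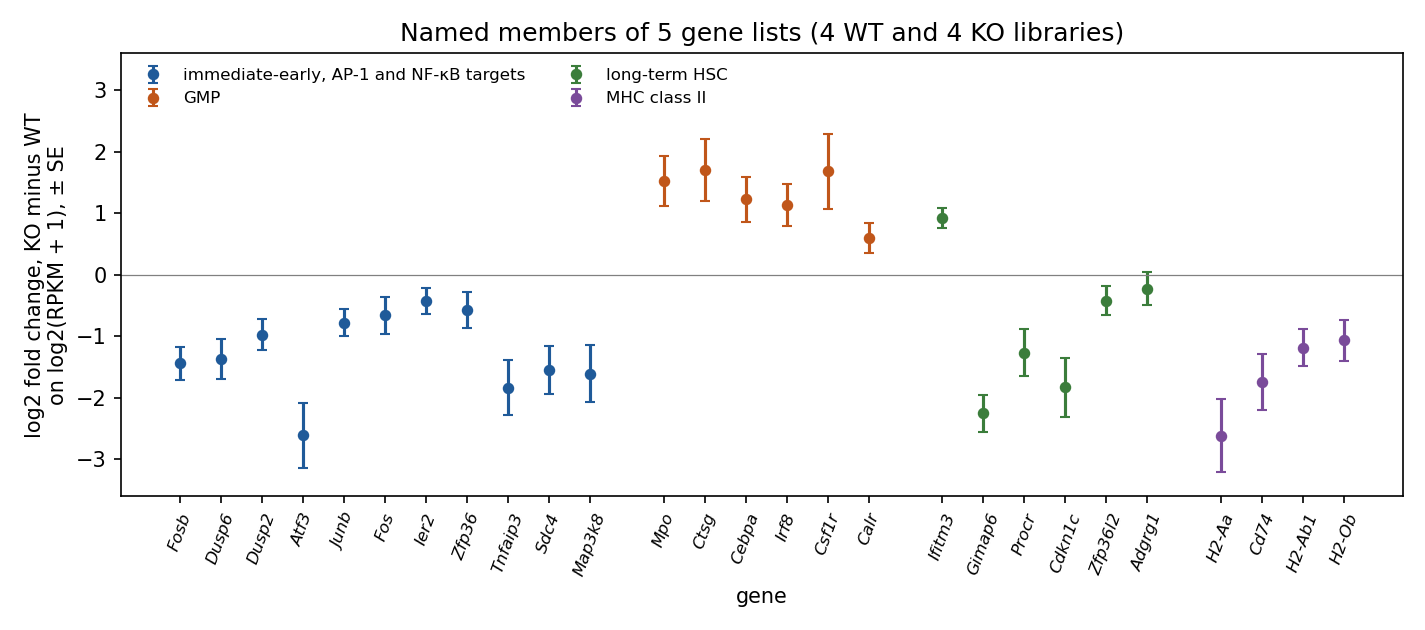
Log2 difference in RPKM + 1 (KO minus WT, limma estimate ± SE, n = 4 per group) of named members of the immediate-early and NF-κB, granulocyte-monocyte progenitor, long-term stem cell and MHC class II lists. Fosb lay at -1.44 ± 0.27 and Mpo at 1.52 ± 0.40; no gene shown passed an adjusted p of 0.05 over all genes.

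Chaperones and folding enzymes of the unfolded protein and heat shock responses rose as a group. Of 31 tested members 23 had positive log2 differences, and the list level was 2.23 ± 0.10 in WT and 2.62 ± 0.22 in KO (difference 0.39, camera adjusted p = 7.3e-06). With an estimated correlation the adjusted p = 0.329, and the exact permutation p was 0.0286, with all KO levels above all WT levels. Adjusted over the list alone, Hsph1, which encodes a heat shock protein of the HSP110 family, rose from 17.9 ± 2.08 to 33.1 ± 2.06 RPKM (0.86 ± 0.20); it passed without KO3 and in none of the other 7 fits that left out a library. The disulfide isomerase genes Pdia4 and Pdia6 were at 23.5 ± 4.91 and 45.7 ± 13.2 RPKM (0.92 ± 0.26) and at 142 ± 26.1 and 207 ± 42.4 (0.54 ± 0.20), and Sdf2l1 at 42.6 ± 15.6 and 84.8 ± 28.8 (1.0 ± 0.33). Hsp90aa1, among the most abundant members, was at 1705 ± 596 and 2091 ± 459 RPKM. The list difference was 0.44 in lane 4 alone, 0.48 without WT2, KO3 and KO4 and 0.21 with quantile normalization (adjusted p = 0.00326).

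Genes of glycolysis rose as a group, with 14 of 20 members positive and a list level of 2.03 ± 0.03 in WT and 2.38 ± 0.20 in KO (difference 0.35, camera adjusted p = 0.00156). With an estimated correlation the adjusted p = 0.329, and the exact permutation p was 0.0286. No member passed the threshold, over all genes or adjusted over the list alone. Pgam1 was at 155 ± 18.2 and 313 ± 112 RPKM (0.94 ± 0.26), Tpi1 at 283 ± 56.9 and 413 ± 55.7 (0.56 ± 0.19) and Gapdh at 856 ± 95.2 and 1125 ± 405 (0.33 ± 0.24), whereas the glucose transporter gene Slc2a3 was at 39.5 ± 11.9 and 23.0 ± 7.28 (-0.76 ± 0.33). The list difference was 0.39 in lane 4 alone, 0.40 without WT2, KO3 and KO4 and 0.19 with quantile normalization (adjusted p = 0.0291). Oxidative phosphorylation genes lay higher only relative to all genes, since the list's own mean log2 difference was 0.012. Of its members 36 of 61 were positive. The list level was 2.83 ± 0.17 in WT and 3.04 ± 0.16 in KO, a difference of 0.21 (camera adjusted p = 0.00175). The adjusted p with an estimated correlation was 0.346, and the exact permutation p was 0.171. No member passed the threshold in limma, over all genes or over the list alone. The respiratory chain genes Ndufa2 and Cyc1 were at 269 ± 10.3 and 441 ± 141 RPKM and at 63.1 ± 13.3 and 91.4 ± 15.4, and Atp5b at 709 ± 67.5 and 818 ± 124. The difference turned to -0.02 with quantile normalization (adjusted p = 0.614), was 0.14 without WT2 (0.0520), 0.12 with library weights (0.111) and 0.06 over genes above 20 RPKM on average (0.0993). It was 0.25 in lane 4 alone and 0.17 without WT2, KO3 and KO4.

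Cell cycle genes gave no group call. The S phase list was at 1.48 ± 0.04 in WT and 1.67 ± 0.10 in KO (difference 0.19, 0.02 with quantile normalization, camera adjusted p = 0.128, exact permutation p = 0.0286), with Mcm7 at 262 ± 43.7 and 245 ± 26.1 RPKM and Pcna at 244 ± 60.9 and 237 ± 38.2. The G2 and M phase list was at 1.46 ± 0.03 and 1.49 ± 0.24 (difference 0.03, adjusted p = 0.408, with camera's direction downward), with Hmgb2 at 386 ± 38.0 and 341 ± 101 RPKM and Cks1b at 287 ± 36.4 and 256 ± 20.8. Its sign depended on the libraries: in lane 4 alone the difference was -0.18 (adjusted p = 0.0138), and the list passed downward in 5 of 22 settings. Of the 6 cyclin-dependent kinase inhibitors tested, 3 fell when adjusted over the list alone: Cdkn1c, Cdkn1b, which encodes p27, at 36.2 ± 3.17 and 18.8 ± 7.80 RPKM (-1.0 ± 0.30), and Cdkn2c, which encodes p18, at 20.3 ± 5.16 and 10.7 ± 4.68 (-0.92 ± 0.34). The count of 3 became 0 without WT2, WT3 or KO4, 1 without KO1 and 2 without WT1 or KO3. Cdkn1a was at 55.2 ± 50.1 and 37.3 ± 17.9 RPKM, Cdkn2d at 12.2 ± 8.13 and 14.2 ± 4.07, and Cdkn3 was at 0 in WT2, at 12.3 to 29.1 RPKM in the other WT libraries and at 9.70 to 54.3 in KO. As a group the inhibitors did not pass (difference -0.21, camera adjusted p = 0.124), but they passed in 6 of 21 settings: without WT2 (-0.51, 0.0198), without KO3 (-0.48, 0.0386), in lane 4 alone (-0.57, 0.0304), with lane as a covariate (-0.57, 0.0141), with library weights (-0.65, 0.0125) and without WT2, KO3 and KO4 (-0.88, 0.00135). In other settings the difference of the inhibitor list (cyclin-dependent kinase inhibitors) nearly vanished, at -0.04 without KO1 and -0.06 without WT1.

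The other lists of intracellular programs did not pass with camera, and none had a member past the threshold in limma, over all genes or adjusted over the list alone. The p53 target list had 25 of 31 members negative (difference -0.32, camera adjusted p = 0.0593, exact permutation p = 0.0286), with Ei24 at 35.9 ± 4.62 and 41.1 ± 25.5 RPKM. It passed in 11 of 22 settings, among them without WT3 (-0.36, 0.0493), WT4 (-0.38, 0.0470), KO3 (-0.37, 0.00274) or KO4 (-0.35, 0.0433) and in lane 4 alone (-0.44, 9.7e-04). The TGF-β and BMP list had 18 of 23 members negative (difference -0.35, camera adjusted p = 0.0887); Tgfb1 was at 179 ± 16.1 and 223 ± 22.3 RPKM and Eng at 23.3 ± 4.31 and 24.5 ± 8.37. It passed in 3 of 21 settings, among them lane 4 alone (-0.41, 0.0211). Interferon response genes did not pass as a group (difference -0.07, camera adjusted p = 0.709), with Ly6e at 499 ± 62.2 and 589 ± 124 RPKM and Psmb8 at 222 ± 29.8 and 218 ± 46.5; the list passed in 3 of 22 settings, among them lane 4 alone (-0.30, 0.0304), and without KO1 the difference was 0.14. Apoptosis regulators had a mean difference of -0.10 and a median of 0.05 (camera adjusted p = 0.731), with Mcl1 at 142 ± 62.9 and 97.2 ± 28.9 RPKM and Casp8 at 59.2 ± 4.45 and 54.9 ± 10.1. Cytosolic ribosomal protein genes had a difference of 0.19 (camera adjusted p = 0.383), with Rps2 at 4147 ± 1026 and 4907 ± 984 RPKM and Rpl41 at 3154 ± 737 and 4145 ± 377; the list passed in both directions, upward without WT4 (0.24, 0.0224) and downward with quantile normalization (-0.10, 0.0291).

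Markers of cells outside the sorting gate were mostly low. Of 22 neutrophil genes listed 7 could be tested, with a mean difference of 1.11 and a median of 0.10 relative to all genes (camera adjusted p = 0.124; past the threshold in 2 of 21 settings). Adjusted over the list alone Pglyrp1 rose, from 0, 0, 3.77 and 7.54 RPKM in WT to 17.4, 9.89, 61.6 and 33.5 in KO; it did not pass without KO4. Lyz2 was at 152 ± 23.2 and 148 ± 23.5 RPKM and Anxa1 at 59.6 ± 15.5 and 49.1 ± 30.7. The monocyte, macrophage and dendritic cell list had a mean difference of 0.11, a median of -0.26 and an upward camera direction (adjusted p = 0.793). Ccr2 was at 47.1 ± 8.07 and 16.0 ± 14.3 RPKM, and Ly6c2 at 3.36, 0, 29.8 and 19.4 in WT and 67.0, 43.9, 32.1 and 0 in KO. Megakaryocyte-erythroid progenitor genes differed by 0.16 (adjusted p = 0.343), with Car1 at 87.2 ± 30.9 and 85.8 ± 61.3 RPKM and Lyl1 at 64.0 ± 15.4 and 81.2 ± 6.23, and by 0.48 without KO1 (0.00407). Late erythroid genes differed by -0.73 (adjusted p = 0.124); Hbb-b2 and Hbb-bt carried identical values, 15.8 to 87.9 RPKM in WT and 43.9, 29.4, 35 and 0 in KO.

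Of 24 B cell genes listed 5 could be tested, with a mean difference of -0.10 and a median of 0.00 (camera adjusted p = 0.770). Cd79b was at 9.5 ± 5.42 and 13.1 ± 4.32 RPKM. Cd74, an MHC class II gene that many antigen-presenting cells express, was the member that fell when adjusted over the list alone, though not without WT3 or KO4. T and NK cell genes had a mean difference of 0.02 and a downward camera direction (adjusted p = 0.793). Adjusted over that list alone Ubash3a rose, from 4.60 ± 2.5 to 17.2 ± 3.20 RPKM, and Lck fell, from 27.2 ± 8.46 to 9.29 ± 9.09 RPKM. Lck kept its call without KO2 and lost it in the other 7 fits that left out a library. Lat was at 22.7 ± 5.58 and 15.0 ± 3.71 RPKM. Mast cell, basophil and eosinophil genes had a mean difference of 0.23 and a median of -0.09 (adjusted p = 0.731), with Srgn at 551 ± 83.0 and 390.0 ± 71.5 RPKM and Cpa3 at 39.2 ± 13.9 and 56.2 ± 14.6. Stromal and endothelial genes differed by -0.06 (adjusted p = 0.697), with Tie1 at 37.9 ± 12.5 and 24.6 ± 8.25 RPKM and Egfl7 at 32.5 ± 9.28 and 28.9 ± 3.94. Transcripts of the sorted markers, chosen after their values were seen, were at similar levels: Kit at 78.4 ± 4.24 and 74.8 ± 27.3 RPKM, and Ly6a, which encodes Sca1, at 10.1 ± 2.07 and 8.84 ± 2.16.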

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

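All tests that weigh an explanation in this part were chosen after the result they bear on had been seen.

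Immediate-early and AP-1 genes lay lower in KO. A loss of transcripts in the libraries that list the fewest genes argues for a difference near 0 without WT2, KO3 and KO4, but there it was -1.132 ± 0.378 (SE). That lay below 0 by more than 2 SE, but within 2 SE of a bound of -0.4 set first. With all libraries the difference was -0.67, so it did not shrink without those libraries. With only KO1 and KO2 on the KO side, 2 SE is too narrow a limit to exclude 0. A loss of transcripts is therefore not decided as a cause. A handling difference that moves heat-inducible genes along with them was examined on 11 heat-inducible genes. They lay above the list without its 2 heat-inducible members (31 genes) by 1.02 ± 0.39 (0.29 ± 0.12 against -0.73 ± 0.38). These did not move together, but most of the 11 belong to the unfolded protein and heat shock list already seen to lie higher. The outcome was thus known beforehand, and -0.73 lay within 2 SE of 0, so this comparison does not decide about handling. A direct or indirect effect of the genotype may account for the pattern, as a hypothesis found on the same data, and handling that acts on immediate-early genes alone was not tested.

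Granulocyte-monocyte progenitor genes lay higher and long-term stem cell genes lower in KO. Mature neutrophils among the sorted cells, which hold S100a8 and S100a9 far above Mpo, are argued against as the source of the Mpo gain. S100a8 and S100a9 gained 14.2 ± 8.43 RPKM together while Mpo gained 1424 ± 551. The ratio was 0.00994 and reached 0.0218 at the upper end of its spread. Neutrophil genes too low to test were uneven: in KO1 S100a8 was at 15.05 RPKM and Wfdc21 at 8.78, and in WT2 Ngp was at 10.28. Less mature granulocyte cells were not tested. Progenitors without Sca1, which the sorting gate would remove, cannot be told apart, since Ly6a lay above the stem cell list by 0.59 ± 0.42 (log2), within 2 SE. For the stem cell genes, a loss of transcripts in the libraries that list the fewest genes is not decided. Without WT2, KO3 and KO4 the difference was -0.602 ± 0.212 (SE) against -0.571 with all 8 libraries, so it did not shrink. It lay below 0 by more than 2 SE, but within its SE of a bound of -0.4 set first. With only KO1 and KO2 on the KO side, 2 SE is too narrow a limit to exclude 0. A shift of the LSK fraction toward myeloid-primed cells in KO may be present, as a hypothesis that these values do not settle.

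MHC class II genes lay lower in KO. B cells among the sorted WT cells stay open: Cd79a, Cd79b and Ms4a1 together gained 3.56 ± 3.47 RPKM in KO while Cd74 lost 118 ± 39.1, a ratio of loss of -0.0301, but Cd79b alone was above 0 in any library, and a single gene decides nothing. Dendritic cells among the sorted WT cells stay open as well: Itgax, Clec9a, Xcr1 and Siglech differed from the class II list by 0.17 ± 0.31 (log2) and fell by 0.86 ± 0.35. Of 5 genes chosen these 4 were above 0 in any library, and Cd209a, listed at 0 in all 8, was left out. The highest mean over the 8 libraries was 4.67 RPKM, and the lineage-negative Sca1+ Kit+ gate would remove such cells. No test separated these explanations from an effect of the genotype.

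Each split of the 8 libraries into 4 and 4 was tested in turn. With limma the real split called 0 genes, a count that all 35 splits reach by construction, so the splits test nothing there and do not exclude chance; the highest other gave 11, with WT1, WT2, KO3 and KO4 on one side. With library weights the real split called 164 genes and the highest other split 25, so 1 of 35 splits gave as many. That share is the smallest possible, and the fit was chosen after the data were seen. The count was 0 without KO1, 1 without KO2 and 0 with the replicate block, so chance is not excluded there either. For the gene lists the real split called 8 and the highest other split 9, with KO2 in the place of WT4, and 3 of 35 splits gave at least 8, so chance cannot be excluded.

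Of 282 groups of 4 values, 26 held a library far from the other 3, 8 in WT and 18 in KO, where chance gives about 1 in 20. KO4 accounted for 7 of them. The number of genes listed above 0 was 11169 in WT2 against 12754 to 12970 in the other WT libraries. In log2(RPKM + 1), Tgfb1 was at 7.67 in WT4 (others 7.41 to 7.45) and 8.01 in KO2 (7.71 to 7.76). Ier5 was at 4.45 in WT4 (5.21 to 5.32), Csf1r at 0.625 in WT1 (2.41 to 2.76), Cdkn2d at 0.615 in WT2 (3.86 to 4.34) and Emp1 at 2.13 in WT2 (3.61 to 3.84). Within KO, KO4 was at 0 for Ly6c2 (5.05 to 6.09) and for Hbb-b2 and Hbb-bt (4.93 to 5.49 each). KO4 was also at 2.94 for Cd79b (3.96 to 4.10), 2.84 for Faap24 (3.57 to 3.61) and 3.96 for Procr (2.68 to 2.78). KO3 was at 11.8 for Rps2 (12.3 to 12.4), 5.35 for Casp8 (5.88 to 5.96), 5.79 for Cdkn3 (3.42 to 3.69) and 4.57 for Itgam (2.79 to 2.94). KO1 was at 3.74 for Tie1 (4.82 to 4.96), 5.83 for H2-Ab1 (6.92 to 7.01) and 8.09 for Pdia6 (7.49 to 7.58), and KO2 at 0.895 for Gbp2b (0 in the others) and 0.589 for Atf3 (0 to 0.02). Among list levels, monocyte, macrophage and dendritic cell genes were at -1.82 in WT1 (-1.44 to -1.36) and -1.82 in KO4 (-1.27 to -1.24). Cyclin-dependent kinase inhibitors were at -0.76 in WT2 (0.36 to 0.59) and interferon response genes at -0.58 in KO1 (0.18 to 0.30).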

How the results depend on the processing

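Library weights, quantile normalization, centring, the covariate for genes listed, the limit to genes above 20 RPKM on average, leaving out WT2, KO3 and KO4 and the exact permutation of lists were chosen after the results were seen. Over 112 named genes and 2310 alternatives, 2186 kept direction and side of the threshold, 49 gained a call, 0 lost one and 75 changed sign in 19 genes. No named gene was called in the main fit, so none could lose a call and this count does not measure stability. Most of the gains came with library weights, and genes called in that fit had been added to the named genes. Over 26 lists and 535 alternatives, 443 kept direction and side of the threshold, 40 gained a call, 13 lost one and 39 changed sign in 11 lists. These counts and the next hold only for camera with its preset correlation: all 8 called lists lost their call with an estimated correlation (smallest adjusted p = 0.327) and with fry (0.0757). The exact permutation (0.106) could hardly pass a list with 8 libraries. Of the 8 called lists, 5 passed in all 22 settings of the preset correlation; NF-κB targets passed in 14, oxidative phosphorylation in 18 and MHC class II in 20. The cause of the changes below was not tested. The alternatives that need counts, DESeq2, limma-voom, DESeq2 size factors and library totals without TMM, were not run because the values are RPKM. Depth limits mainly low genes, and 0 values in KO3, KO4 and WT2 affect abundant genes as well.

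The count of 0 genes became 2 in lane 4 alone (2 lower), 3 without WT2, KO3 and KO4 (3 lower: Gem, Jchain and Emp1) and 164 with library weights (67 higher, 97 lower), and ranged from 0 to 2 when each library was left out (0 to 2 lower). At an adjusted p under 0.1 or with a fold minimum it was 0. The Traf6 difference passed with weights (-2.525, adjusted p = 0.00785); its adjusted p lay between 0.107 and 0.889 in the other settings. The count of 8 lists became 14 with lane as a covariate, 13 in lane 4 alone, 13 without WT2, KO3 and KO4, and 0 with an estimated correlation, with fry or with the exact permutation. The weighted count of 164 became 59 with lane as a covariate, 49 in lane 4 alone, 3 with no filter, 6 without WT2, KO3 and KO4, and ranged from 0 to 248 when each library was left out. Of the 164 genes, 53 remained called with lane as a covariate and 46 in lane 4 alone.

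Libraries with the same number did not deviate together (correlations -0.053, -0.080, -0.038 and -0.064), so the values show no pairing by number. The strong deviations of KO3, KO4 and WT2 could hide a pairing, so none is excluded. With the replicate block limma called 0 genes (0 with weights) and camera 12 lists.

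List differences that changed sign (log2, relative to all genes) were, with no filter, stromal and endothelial 0.021 and G2 and M phase -0.005; with lane as a covariate or lane 4 alone, megakaryocyte-erythroid -0.261, T and NK cell -0.149, G2 and M phase -0.183 and apoptosis 0.021. With a pseudocount of 0.1 they were monocyte, macrophage and dendritic cell -0.094 and stromal and endothelial 0.068; with weights, B cell 0.127, T and NK cell -0.065 and G2 and M phase -0.146. With quantile normalization they were B cell 0.077, G2 and M phase -0.155, oxidative phosphorylation -0.022 and ribosomal protein -0.095; with genes listed as a covariate, T and NK cell -0.064 and G2 and M phase -0.032. Without WT2, KO3 and KO4 they were megakaryocyte-erythroid -0.254, B cell 0.103, T and NK cell -0.139 and G2 and M phase -0.192; over genes above 20 RPKM, multipotent progenitor 0.004, G2 and M phase -0.049 and interferon 0.018. With each library left out the lists ranged as follows: monocyte, macrophage and dendritic cell -0.002 to 0.246, B cell -0.217 to 0.076, stromal and endothelial -0.123 to 0.057, T and NK cell -0.187 to 0.113, interferon -0.156 to 0.138, megakaryocyte-erythroid -0.004 to 0.482, G2 and M phase -0.045 to 0.107.

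Gene differences that changed sign (log2) were, with lane as a covariate or lane 4 alone, Anxa1 0.075, Mcm7 0.042, Pcna 0.063, Ei24 0.004, Psmb8 0.158, Eng -0.146, Casp8 0.042, Nfkb1 0.084 and Nfkb2 0.224. With weights they were Mcm7 0.056, Ei24 0.096, Psmb8 0.222, Casp8 0.068, Cdkn2d -0.231, Cdkn3 -0.272 and Nfkb1 0.064. With quantile normalization they were Rps2 -0.049 and Nfkb2 0.117; with genes listed as a covariate, Pcna 0.020, Psmb8 0.027, Eng -0.012 and Nfkb2 0.067. Without WT2, KO3 and KO4 they were Mcm7 0.10, Cks1b 0.018, Ei24 0.066, Psmb8 0.144, Eng -0.053, Casp8 0.092, Cdkn2d -0.535, Cdkn3 -0.717 and Nfkb1 0.023. Eng was at -0.017 without ribosomal protein, haemoglobin and mitochondrial genes and -0.001 with centring. With each library left out the genes ranged as follows: Adgrg1 -0.421 to 0.037, Lyz2 -0.158 to 0.057, Anxa1 -0.971 to 0.073, Car1 -0.977 to 0.379, Pcna -0.180 to 0.122, Cdkn1a -0.721 to 0.251, Ei24 -0.360 to 0.363, Psmb8 -0.177 to 0.058, Ndufa4 -0.196 to 0.142, Eng -0.160 to 0.199, Casp8 -0.184 to 0.019, Cdkn2d -0.197 to 1.046, Cdkn3 -0.132 to 1.505, Nfkb1 -0.187 to 0.177, Nfkb2 -0.500 to 0.190, Kit -0.348 to 0.034.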

Other observations

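Replication-dependent genes of histone H2A were higher in KO, a group picked and tested after its values had been seen. All of the 16 H2A cluster genes tested but 1 had positive log2 differences, 6 had all KO values above all WT values, and 13 had an unadjusted limma p under 0.05. Their mean level relative to all genes was 2.81, 2.41, 3.09 and 3.43 in WT1 to WT4 and 3.50, 4.16, 4.10 and 4.29 in KO1 to KO4, a difference of 1.08 ± 0.28 (SE; 2-sided exact permutation p = 0.0286, the smallest possible). The median over genes and libraries was 150.5 RPKM in WT and 307 in KO, and H2ac6, for example, was at 150 to 258 RPKM in WT and 267 to 552 in KO. The difference was 0.83 with quantile normalization, 0.90 in lane 4 alone and 0.73 without WT2, KO3 and KO4.

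The other classes of clustered histone genes were not tested against H2A, and most of their members were listed at 0 in at least 1 library. H1, H2B, H3 and H4 genes differed by -0.31 ± 0.64, -0.82 ± 0.76, -0.58 ± 0.55 and -0.21 ± 1.18, with exact permutation p of 0.657, 0.314, 0.429 and 0.571, and 12 of the 15 H2B genes tested were listed at 0 in KO3. A larger share of cells in S phase was tested as a candidate explanation and stays open. Relative to all genes the S phase list differed by 0.19 ± 0.05, with every KO level (1.56 to 1.79) above every WT level (1.44 to 1.53). It did not pass with camera (adjusted p = 0.128), its own mean log2 difference was -0.006, and relative to all genes the difference was 0.015 with quantile normalization, so a rise is not settled. The difference lay below 0.5 of the H2A difference by 0.35 ± 0.14 (-0.348 in log2, SE 0.139), but how far the list would move with a larger share was not measured. H2A genes are nearly identical copies that share reads, and most replication-dependent histone transcripts lack a poly(A) tail, so a difference in how the libraries captured them may remain and was not tested.

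Xist was above 0 in all 8 libraries, and the Y-linked genes were mostly listed at 0. Xist was at 107, 201, 145 and 71.2 RPKM in WT1 to WT4 and at 45.7, 68.8, 82.0 and 100.1 in KO1 to KO4. Ddx3y was at 1.79 RPKM in WT1 and 10.9 in KO3 and listed at 0 elsewhere, and Eif2s3y was at 0.405 RPKM in KO1 and listed at 0 elsewhere. Kdm5d and Uty were listed at 0 in all 8 libraries.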
